A study of Mus musculus with 4 samples.

How the data were processed

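Total RNA from mouse embryonic fibroblasts on day 3 after infection was extracted with Trizol, and biotin-labelled sense-strand target was made from 100 ng by the Affymetrix whole-transcript assay, per the labels' protocols. There were 4 samples in 4 groups, with 1 array per group: OK cells (Oct4, Klf4 and TetOn-Sox2) without and with doxycycline, and OS cells (Oct4, Sox2 and TetOn-Klf4) without and with doxycycline. Groups were taken from the titles and the characteristics. A source label of the induced OS sample names the other virus set, against its title and its other labels.

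The values deposited by the authors are 1 number per probeset and array for 28853 probesets. RMA and Partek are named in the submitters' processing notes; their versions, and the arrays that were normalised together, are not given in the sources used here. RMA gives log2 values after background correction and normalisation in its usual form, and the deposited values were read as log2 from their range and from the nearly equal quartiles of the 4 arrays. Such a normalisation gives the arrays nearly the same distribution, so a shift of most transcripts in a single direction would not be seen. No detection call or signal over background was used, so dim genes are judged only by their level.

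The platform annotation lists 23410 of the probesets, 21789 with a single gene symbol and 1621 with several; 5443 are not listed and are unnamed here. Of the probesets with a single symbol, 21698 matched a RefSeq gene (GRCm38.p6) by gene identifier, and 0 symbols needed an update. Probesets of the same symbol were averaged, which concerned 999 genes, and gave 19938 genes. Probesets with several symbols were not named or counted. Some well-known list members were therefore not measured by a probeset with a single symbol.

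A difference is the log2 value on the first array minus that on the second: induced minus uninduced for each induction, and OK minus OS for the uninduced and for the induced cells. The difference between the inductions is the Sox2 difference minus the Klf4 difference. Genes with a difference of at least 2-fold in either direction were counted. No test was run, because each group has 1 array. As a gauge of noise among dim genes, the same count was made among the 1994 genes with the lowest mean over the 4 arrays; this gauge was chosen after the data were examined. Overlaps of counts were set beside the number that independent lists of the same sizes give.

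Before the data were examined, 27 gene lists were fixed, of which 659 of 713 distinct members were measured. They were pluripotency, epithelial, squamous epithelial, mesenchymal regulator and cytoskeleton, extracellular matrix, and fibroblast surface and identity genes; TGF-beta, BMP and WNT pathway genes; and DNA replication, mitosis, and p53 and senescence genes. The others were interferon and antiviral, inflammatory and senescence-secretory, immediate early, integrated stress response, glycolysis and hypoxia, and sterol synthesis genes, then primitive endoderm and mesendoderm, trophoblast and neural genes. Markers of macrophages and leukocytes, endothelium, muscle, and adipocytes and cartilage were included as other cell types that a fibroblast culture can hold, with ribosomal protein genes and common reference genes. The delivered factors were left out of every list. For each list the median difference was set beside those of 10000 random lists of the same size, matched on mean expression in 20 bins; the central 95% of their medians is called the random range. This describes the 4 arrays and is not a test.

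Genes were named by a rule fixed at the same time. It takes the delivered factors and Myc, the 12 largest differences each way in each induction, and the 6 largest each way in the uninduced comparison, in the induced comparison and in the difference between the inductions. These were taken among the 11127 genes whose highest value reached 4.69, the median of all gene values, here called brighter genes. It also takes up to 4 members of each list with the largest absolute difference in the comparison spoken of. Unnamed models, predicted genes and receptor families listed in the rule were passed over. Other genes are named only with a statement that they were chosen after their values were seen, or as members of an overlap.

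Alternatives planned in advance were thresholds of 1.5-fold and 3-fold, brighter genes only, arrays shifted to a common median, quantile normalisation, loess of the difference on the mean level (span 0.3), the probeset with the highest mean or the largest difference in place of the average, and random lists without matching. Added after the data were examined were the subtraction of a trend over gene span and gene density and the removal of those 1994 dim genes. The induced comparison, which leaves out the uninduced OS array, was also looked at again then, but it is no alternative measure of Klf4 induction. Gene span and density came from RefSeq positions (GRCm38.p6) for 19919 genes, with 10 neighbours on each side for density; no coordinates are given. No genome sequence was used, so GC content was not examined.

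The counting and list steps were tested on simulated data for Sox2 induction over 19938 genes with a noise SD of 0.2, in which 100% of 200 genes changed by a log2 difference of 2 were recovered and 16 unchanged genes passed the threshold. On simulated data for Klf4 induction over the same genes, a list raised by a log2 difference of 1 lay at percentile 100 and an unchanged list at percentile 1.11, outside the central 95%. Of 100 further unchanged lists of 30 genes, 5 lay outside it, so a few of the 27 lists can lie outside the range with no change. The simulated noise was independent between genes, however, whereas members of a real list can vary together between single arrays. How many of the 27 lists can lie outside the range without an effect of a factor is therefore not known, and may be more. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.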

Results

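Gene expression was measured in mouse embryonic fibroblasts on day 3 after infection with viruses that carried reprogramming factors, a stage early in the path towards induced pluripotent cells. The fibroblasts had the 129/OG2 genetic background, and all cells were kept in iCD1, a medium described by the submitters as optimised for reprogramming. OK cells received retroviruses for Oct4 and Klf4 together with a virus in which Sox2 is switched on by doxycycline. OS cells received retroviruses for Oct4 and Sox2 together with a virus in which Klf4 is switched on by doxycycline. Each kind of cell was profiled without doxycycline (uninduced) and with it (induced), on 1 Affymetrix whole-transcript array each, which gives 4 arrays in 4 groups. There were no replicates, so no difference below has a replicate check, no p-value is given, and the number of arrays limits the precision of every value. The medians of the log2 values over all 28853 probesets lay between 4.41 and 4.45 on the 4 arrays. Among the 1994 genes with the lowest mean level, where little expression is measured, 0.552% to 0.953% differed by at least 2-fold in the 4 comparisons of pairs of arrays, and that share is set beside their counts as a gauge of noise among dim genes only. These genes were picked by their mean over the same 4 arrays, which tends to leave out genes high on any of them. The share may therefore be low, and it does not measure noise among brighter genes. No measure of signal over background was used, so where the lower value of a gene lay under the first quartile of its array, 3.04 to 3.05, its difference is read as a bound whose rank is not firm, and such genes are named.

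The transcripts of the delivered factors were examined first, because they bear on the labels. Sox2, a pluripotency and neural transcription factor, had log2 values of 4.13 in uninduced and 5.01 in induced OK cells, a difference of 0.89 or 1.85-fold that ranked 167 of 19938 genes. Klf4, a zinc-finger transcription factor also active in skin and gut epithelium, had values of 7.29 in uninduced and 8.22 in induced OS cells, a difference of 0.93 or 1.90-fold that ranked 875. In the cells that carried them on a retrovirus throughout, Sox2 stood at 5.26 and 4.86 in uninduced and induced OS cells, and Klf4 at 7.70 and 7.96 in uninduced and induced OK cells. Pou5f1, which encodes Oct4 and was delivered to all cells, had values of 10.64 and 10.52 in OK cells and of 10.75 and 9.63 in OS cells, so that it was lower by a log2 difference of -1.12 in the induced OS cells. Myc, the remaining classical reprogramming factor, was not delivered; it stood at 6.07 and 6.11 in OK cells, at 5.05 in uninduced OS cells and at 7.15 in induced OS cells. Each induced factor was higher with doxycycline, as its label states. Where the probes lie relative to the transgenes is not given in the sources used here, so these values may mix virus-borne and endogenous transcripts. A source label of the induced OS sample names the virus set of the OK cells, whereas its title and all its other labels name the OS set; the title was followed, and the values do not settle which is right.

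**Figure D1:**
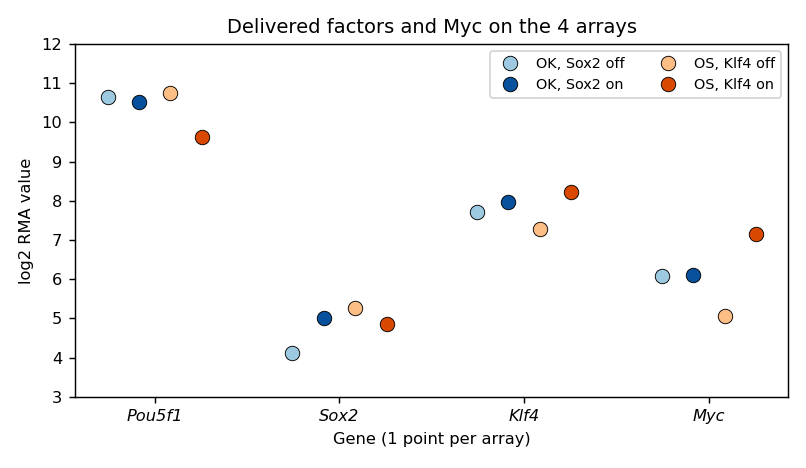
Log2 RMA values (vertical axis) of Pou5f1, Sox2, Klf4 and Myc, with 1 point per array and colours for the 4 arrays. Sox2 was lowest in uninduced OK cells at 4.13, Klf4 was lowest in uninduced OS cells at 7.29, and Myc was highest in induced OS cells at 7.15.

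Sox2 induction in cells that already carried Oct4 and Klf4 was examined by setting induced against uninduced OK cells. The induced cells also received doxycycline, and no array shows the drug without an inducible factor. Effects of Sox2 and of doxycycline itself therefore cannot be told apart. Interferon-response genes were lower in the induced cells, a small group of genes that includes the transcription factor Sox21 and the neuronal tubulin Tubb3 was higher, and the epithelial genes showed little difference. Of 19938 genes, 117 were at least 2-fold higher and 80 at least 2-fold lower with Sox2 induction, 0.988% in all, against 0.552% of the dimmest genes. The largest differences upward were those of Fndc3c1 at 3.58, Lix1 at 3.13, Esm1, a secreted proteoglycan, at 2.73, Glb1l2, a beta-galactosidase-like protein, at 2.68, and Adh7, an alcohol dehydrogenase that also oxidises retinol, at 2.53. They were followed by Gpr50, an orphan receptor related to the melatonin receptors, at 2.49, Strip2 at 2.46, Ednrb, an endothelin receptor, at 2.39, and Gad2, an enzyme that makes the transmitter GABA, at 2.37. Alg13, which acts in protein N-glycosylation, Tagln3, a neuronal calponin-family protein, and Sox21 differed by 2.35, 2.30 and 2.13. Of these 12 genes, Fndc3c1 and Strip2 lay under the first quartile in uninduced OK cells, so their differences are bounds. The largest differences downward were those of Saa3, an acute-phase serum amyloid, at -2.60, Ifit3 at -2.50, Trim30a at -2.28, Ifit1 at -2.20, Cxcl10, an interferon-induced chemokine, at -1.99, and Rsad2, the antiviral protein viperin, at -1.84. Tomm5, a part of the mitochondrial import channel, Slfn2, Stfa3, Cfb, a complement factor, Olr1, a receptor for oxidised lipoprotein, and Serpinb11 differed by -1.76, -1.65, -1.63, -1.62, -1.54 and -1.52.

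Of 32 measured interferon and antiviral genes, 14 were at least 2-fold lower with Sox2 induction and 0 at least 2-fold higher, and 31 lay below 0. Their median log2 difference was -0.98, and 0 of 10000 random lists matched on mean expression had a median as low. However, 31 of the 32 were also higher in uninduced OK than in uninduced OS cells, with a median of 1.11. The difference with Sox2 induction may thus reflect high values on the uninduced OK array, which has no replicate. Of 27 inflammatory and senescence-secretory genes, 3 were at least 2-fold lower, namely Saa3 at -2.60 and the matrix metalloproteinases Mmp3 at -1.11 and Mmp13 at -1.02, and the median was -0.45, also below all random lists. Neural genes had 2 of 25 members at least 2-fold higher, Sox21 at 2.13 and Tubb3 at 1.75, but their median of 0.11 lay within the central 95% of random lists. Of 29 WNT pathway genes, the secreted antagonist Sfrp4 at 1.19 and the stem-cell receptor Lgr5 at 1.09 were at least 2-fold higher, with a list median of -0.11 inside that range.

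Genes of the fibroblast state differed by small amounts. Extracellular matrix genes had a median of -0.17 over 32 members, TGF-beta pathway genes -0.20 over 24, and mesenchymal regulators and cytoskeletal genes -0.12 over 26, each below the central 95% of random lists with 0 members at least 2-fold apart; the mesenchymal median was inside the range of lists not matched on expression, at percentile 3.23. The median of 26 BMP pathway genes was -0.18, also below that range, and the ligand Bmp2 differed by -1.32. Of 24 fibroblast surface and identity genes, Pdgfrb, a platelet-derived growth factor receptor, was at least 2-fold lower at -1.14, and the list median of -0.10 lay inside the range. Sterol synthesis genes at -0.20 and glycolysis and hypoxia genes at -0.16 lay below it with 0 members at least 2-fold apart. Mitosis genes at 0.19 and DNA replication genes at 0.10 lay above it, also with 0 members at least 2-fold apart, though the replication median was inside the unmatched range at percentile 97.0; the mitotic genes Ube2c and Cenpa differed by 0.75 and 0.68.

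Epithelial genes had a median of -0.03 over 42 members and squamous epithelial genes -0.02 over 27, with 0 members of either list at least 2-fold apart. Pluripotency genes had a median of 0.03 over 36 members, and Tfcp2l1, a transcription factor of naive pluripotent cells, was at least 2-fold higher at 1.30. Trophoblast genes had 1 of 18 members at least 2-fold lower, the transcription factor Ets2 at -1.17, around a median of -0.10. The medians of the p53 and senescence (0.03), immediate early (0.04), integrated stress response (-0.05), primitive endoderm and mesendoderm (-0.08) and ribosomal protein (-0.06) lists lay inside the random range. So did those of the macrophage and leukocyte (-0.05), endothelial (-0.09), muscle (-0.11), adipocyte and cartilage (0.04) and common reference (-0.03) lists, all of these without a member at least 2-fold apart.

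Klf4 induction in cells that already carried Oct4 and Sox2 was examined by setting induced against uninduced OS cells. Effects of Klf4 and of doxycycline itself cannot be told apart here either. Pou5f1 also differed, at -1.12, so the transcript of delivered Oct4 was not constant in this comparison. Keratins and other genes of squamous and simple epithelia were higher in the induced cells, in part by more than any gene differed with Sox2 induction, together with replication and mitosis genes. Many extracellular matrix genes were lower, and the medians of the mesenchymal and TGF-beta pathway lists lay below 0, although most of their members differed by less than 2-fold. Of 19938 genes, 728 were at least 2-fold higher and 841 at least 2-fold lower with Klf4 induction, 7.87% in all, against 0.953% of the dimmest genes. The largest differences upward were those of Krtdap, a keratinocyte differentiation protein, at 6.62, the keratins Krt90 at 6.50, Krt16 at 5.96 and Krt14 at 5.55, the surface antigen Psca at 5.99 and the annexin Anxa8 at 5.80. Next came Aqp3, a water and glycerol channel, at 5.30, Cyp4f39, a cytochrome P450, at 4.93, Ano1, a calcium-activated chloride channel, at 4.90, Upk1b, a uroplakin of bladder epithelium, at 4.87, Slurp1 at 4.84 and Alox12b, a lipoxygenase of the skin barrier, at 4.67. Krtdap, Psca and Krt16 lay under the first quartile in uninduced OS cells, so their differences are bounds. The largest differences downward were those of Lpar4, a lysophosphatidic acid receptor, at -2.92, Necab1 at -2.84, Luzp2 at -2.83, Postn, the matrix protein periostin, at -2.72, Acsl4, an acyl-CoA synthetase, at -2.62, and Manea, an endomannosidase of the Golgi, at -2.56. Lhfpl1, Dmxl2, Hmgn5, Gria3, a glutamate receptor subunit, and Elapor2 differed by -2.51, -2.48, -2.43, -2.40 and -2.36. Probes for members of close families such as the keratins and the Ifit genes can share signal, so the division among such members is uncertain.

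Of 27 measured squamous epithelial genes, 15 were at least 2-fold higher with Klf4 induction and 0 at least 2-fold lower, with a median of 1.67 that exceeded all 10000 matched random lists; Upk1b and Krt13 differed by 4.87 and 4.02. Of 42 epithelial genes, 21 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.998, also above all random lists. Among these were the simple-epithelial keratins Krt8 at 4.25 and Krt19 at 4.06, the 14-3-3 protein Sfn at 3.34, and the desmosomal plakophilin Pkp1 at 3.27. Both medians were larger, at 2.98 and 1.59, when only members whose highest value over the 4 arrays reached the median level were counted. That filter favours members that are high on any 1 array, so larger medians follow in part from the selection. DNA replication genes had 7 of 29 members at least 2-fold higher and 0 lower around a median of 0.83, with Rrm2, a subunit of ribonucleotide reductase, at 1.61 and Mcm3, a part of the replicative helicase, at 1.38. Mitosis genes had 10 of 29 members at least 2-fold higher and 0 lower, also around a median of 0.83, with Anln and the kinase Plk1 both at 1.48. Both medians exceeded all random lists.

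Of 32 extracellular matrix genes, 12 were at least 2-fold lower and 1 at least 2-fold higher, and the median of -0.69 lay below all random lists. Postn at -2.72, the proteoglycan Vcan at -2.18 and the thrombospondin Thbs1 at -2.17 were lower, and the microfibril protein Mfap5 was higher at 2.87. Mesenchymal regulators and cytoskeletal genes had 4 of 26 members at least 2-fold lower and 2 at least 2-fold higher around a median of -0.46, with the protease Fap at -2.07 and the cadherin Cdh11 at -1.63 against the hyaluronan receptor Cd44 at 1.86 and S100a4 at 1.69. TGF-beta pathway genes had 4 of 24 members at least 2-fold lower around a median of -0.38, among them the receptor Tgfbr1 at -1.56 and the activin subunit Inhba at -1.50. The medians of both lists lay below the central 95% of random lists. Fibroblast surface and identity genes went both ways, with Pi16 at 2.90 and the receptors Pdgfrb and Pdgfra at -1.63 and -1.45, and their median was 0.00. Interferon and antiviral genes had 8 of 32 members at least 2-fold lower and 1 at least 2-fold higher, with Rtp4 at -1.57, Parp14 at -1.33 and Oas2 at 1.45, and their median of -0.34 lay below the range.

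Pluripotency genes had a median of 0.13 over 36 members, inside the random range, with Tfcp2l1 at least 2-fold lower at -1.09 and 0 members at least 2-fold higher. Ribosomal protein genes had a median of 0.40 over 20 members, above the range, with 0 at least 2-fold apart. Trophoblast genes had 4 of 18 members at least 2-fold higher and 1 lower, and their median of 0.36 lay above the range; of the members named here, Krt8 and Krt7 also belong to the epithelial list, and Gata2 and Tead4, both transcription factors, differed by 1.82 and 1.26. Neural genes went both ways around 0.05, with the microtubule regulator Stmn2 at 2.59 and Tubb3 at 2.30 against the adhesion molecule Nrcam at -1.74 and Map2 at -1.61. Inflammatory and senescence-secretory genes had a median of 0.05 with Mmp13 at -1.99 and the adhesion molecule Vcam1 at -1.29. Immediate early genes had 2 of 20 members at least 2-fold higher around 0.10, Nr4a1 at 2.26 and Myc at 2.10. The medians of the p53 and senescence (-0.08), glycolysis and hypoxia (0.24), integrated stress response (0.24), sterol synthesis (0.08), primitive endoderm and mesendoderm (0.06), macrophage and leukocyte (-0.06), muscle (0.03) and common reference (0.02) lists lay inside the range. Against lists not matched on expression, the glycolysis and integrated stress response medians lay above the range, at percentiles 98.4 and 98.5. Perp, a p53 target that is also an epithelial junction protein, differed by 2.05, and the reference gene Hprt differed by 1.13.

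The uninduced OS array stood apart from the other 3 arrays, and every Klf4-induction value rests on it. By the labels, its cells were also the only ones without delivered Klf4 switched on. The lack of Klf4 therefore cannot be told from a property of this single array. The uninduced OS array differed by at least 2-fold from all other arrays at 725 genes, against 140 for the induced OS array and 97 for the uninduced OK array. Over all probesets it correlated with the other arrays at 0.961 to 0.971, and those arrays correlated with each other at 0.980 to 0.990. Klf4-induction differences also varied with the length of the gene, from a median of 0.20 in the tenth of brighter genes with the shortest span to -0.35 in the tenth with the longest.

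**Figure D2:**
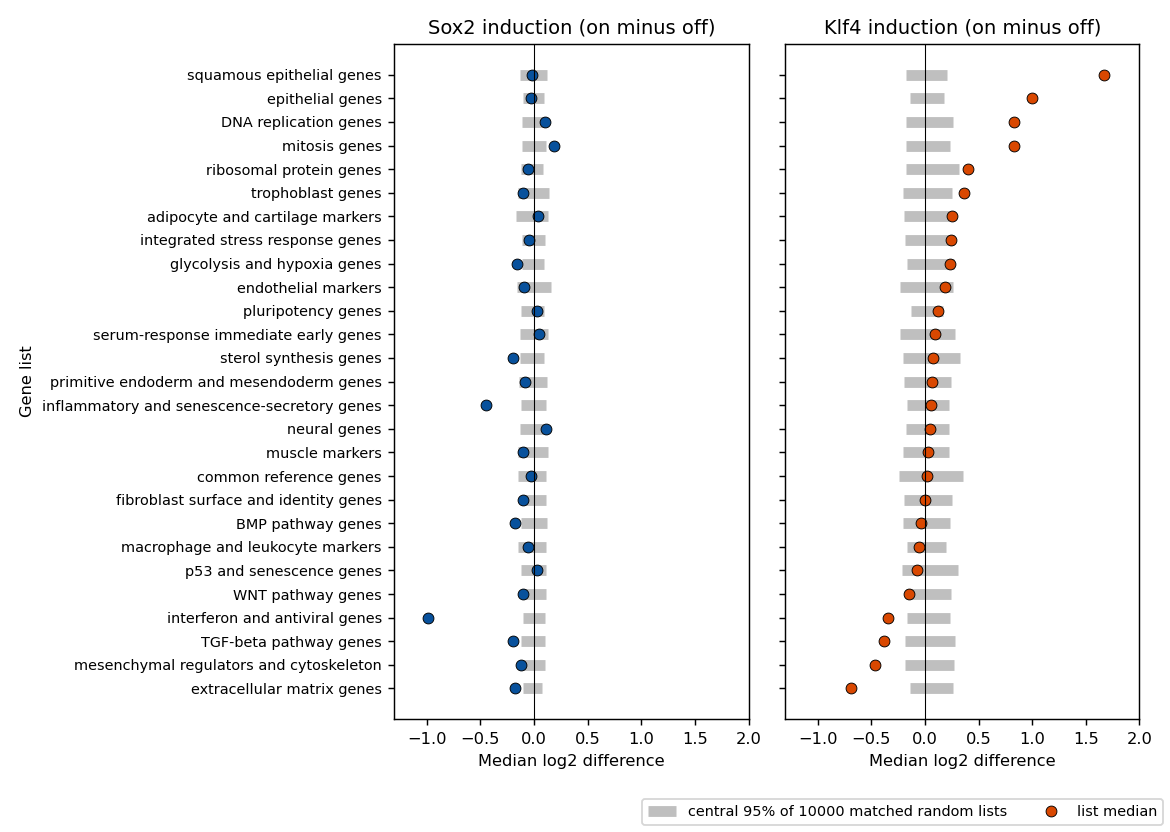
Median log2 difference (horizontal axes, induced minus uninduced) of each fixed gene list (vertical axis) for Sox2 induction and Klf4 induction. Grey bars span the central 95% of 10000 matched random lists and points are the list medians; squamous and epithelial genes reached 1.67 and 0.998 with Klf4 induction, and interferon and antiviral genes reached -0.98 with Sox2 induction.

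Whether both inductions moved the same genes was examined next; they share no array. Genes higher with Sox2 induction were often lower with Klf4 induction, and several interferon-induced genes were lower with both. At least 2-fold higher with Sox2 and at least 2-fold lower with Klf4 were 45 genes, against 4.94 for independent lists of these sizes. Of the 44 of them that reached the median level, all 44 were lowest in uninduced OK cells and all 44 highest in uninduced OS cells, with median log2 values of 4.12 in uninduced OK, 5.65 in induced OK, 7.23 in uninduced OS and 5.53 in induced OS cells. This order is set in part by the selection, which allows only uninduced OK or induced OS cells as lowest. Likewise it allows only induced OK or uninduced OS cells as highest. Across the 19938 genes the log2 differences of the inductions had a Pearson correlation of -0.135 and a Spearman correlation of -0.120; genes are not independent replicates, so these describe the 4 arrays only. At least 2-fold lower with both were 17 genes, against 3.37 for independent lists, among them Ifit3, Ifit1, Trim30a, Parp14 and Pdgfrb. Ifit3 lay under the first quartile in induced OS cells. Doxycycline was added in both inductions, and its own effect on genes moved the same way in both was not tested. At least 2-fold higher with both were 9 genes, against 4.27, among them Tubb3 at 1.75 and 2.30 and Ano1 at 1.73 and 4.90. The remaining combination, lower with Sox2 and higher with Klf4, held 6 genes against 2.92. These expected numbers treat all genes as equally likely to be called. Yet 97 of 117 genes higher with Sox2 and 656 of 728 higher with Klf4 induction were among the 11127 brighter genes. The expected numbers are therefore low, and the small excesses are not read as overlaps.

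The difference between the inductions, Sox2 minus Klf4, was largest upward for Fndc3c1 at 5.80, Glb1l2 at 3.95, Lix1 at 3.85, Gad2 at 3.77, Ednrb at 3.68 and the acyl-CoA synthetase Acss3 at 3.67. It was largest downward for Krtdap at -6.77, Krt90 at -6.61, Psca at -6.34, Anxa8 at -5.94, the epithelial protein S100a14 at -5.41 and Upk1b at -5.31. Those of Fndc3c1, Krtdap, Psca and S100a14 rest on a value under the first quartile of an array. Squamous epithelial genes had a median of -1.81 and epithelial genes one of -1.05, with 16 of 27 and 22 of 42 members at least 2-fold below 0; of all genes 11.5% were at least 2-fold from 0 in either direction, and of the dimmest genes 3.51%. Interferon and antiviral genes had a median of -0.70, DNA replication genes -0.74 and mitosis genes -0.65, and extracellular matrix genes one of 0.53. All these medians lay outside the central 95% of random lists.

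**Figure D3:**
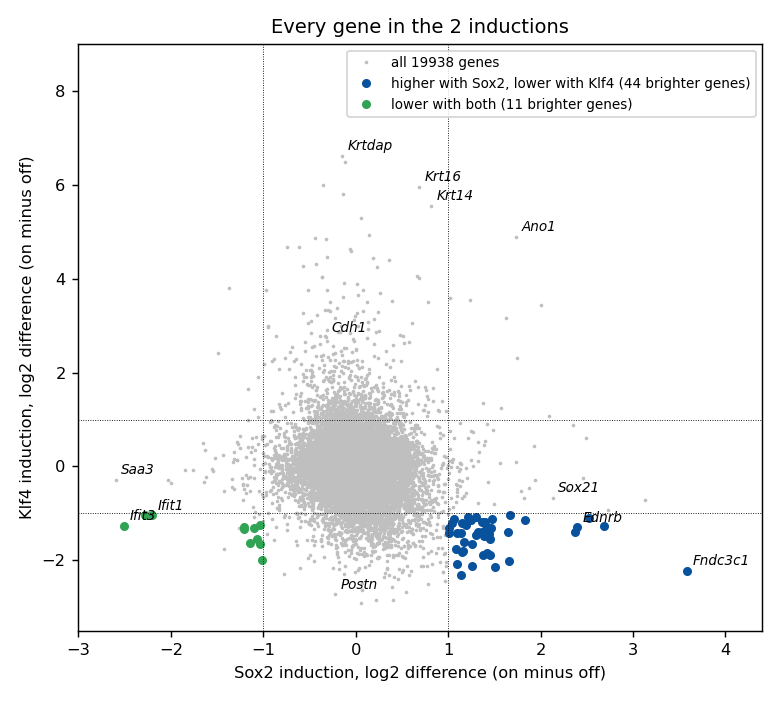
Log2 difference with Sox2 induction (horizontal axis) against that with Klf4 induction (vertical axis), with 1 grey point per gene and dotted lines at 2-fold. Blue points are 44 brighter genes higher with Sox2 and lower with Klf4, and green points are 11 brighter genes lower with both; Krtdap lies at 6.62 on the vertical axis and Fndc3c1 at 3.58 on the horizontal axis, both of them bounds.

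The starting states were compared by setting uninduced OK against uninduced OS cells, which carried Oct4 with Klf4 or with Sox2. Epithelial, interferon and DNA replication genes were higher in OK cells, and extracellular matrix genes were lower. Of 19938 genes, 748 were at least 2-fold higher and 990 at least 2-fold lower in OK cells, against 0.853% of the dimmest genes in either direction. The largest differences upward in OK cells were those of Anxa8 at 6.26, Krtdap at 5.86, Krt90 at 5.26, the surface protein mesothelin, Msln, at 5.21, Psca at 5.14 and the aldehyde dehydrogenase Aldh3a1 at 5.14. The largest downward were those of Spink10 at -5.59, Fndc3c1 at -5.20, Bex1, a neuronal adaptor protein, at -4.58, the adhesion receptor Adgrb3 at -4.55, Prss3, a trypsin family member, at -4.51 and Necab1 at -4.37. Spink10, Fndc3c1, Bex1 and Adgrb3 in OK cells and Krtdap and Psca in OS cells lay under the first quartile, so their differences are bounds.

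Interferon and antiviral genes had 18 of 32 members at least 2-fold higher in uninduced OK than OS cells and 0 lower, with a median of 1.11; Oas2 differed by 2.72 and Irf7, a transcription factor of the interferon response, by 2.03. Squamous epithelial genes had 10 of 27 members at least 2-fold higher and 0 lower around 0.52, with the cornified-envelope protein Sprr1a at 3.71 and Krt14 at 2.88. Epithelial genes had 11 of 42 higher and 1 lower around 0.33, with Krt19 at 3.32, the cell adhesion molecule Cdh1 (E-cadherin) at 2.50 and the plakophilin Pkp2 at -2.43. DNA replication genes had 10 of 29 higher and 0 lower around 0.85, and mitosis genes 1 of 29 higher around 0.50. Extracellular matrix genes had 11 of 32 members at least 2-fold lower and 1 higher around -0.32, with the collagen Col8a1 at -3.34, Postn at -2.98 and Mfap5 at 1.89. Mesenchymal regulators and cytoskeletal genes had 6 of 26 members at least 2-fold higher and 2 lower, against the sign of their median of -0.22, with S100a4 at 2.76 and the smooth muscle actin Acta2 at -2.34. All these medians lay outside the central 95% of random lists. So did those of the p53 and senescence list at -0.41, the sterol synthesis list at 0.46, the glycolysis and hypoxia list at 0.36, the trophoblast list at 0.36 and the primitive endoderm and mesendoderm list at 0.28. Endothelial markers had 3 of 17 members at least 2-fold higher in OK cells around 0.32, also above the range, with Tek at 2.57 and Flt1 at 1.82. Macrophage and leukocyte markers had 3 of 24 members at least 2-fold higher around a median of 0.11 inside the range, with Laptm5 at 2.83 and Cd14 at 1.73. Neural genes had 5 of 25 members at least 2-fold lower in OK cells, with Sox21 at -2.57 and the lipid-binding protein Fabp7 at -2.01, a bound as it lay under the first quartile in OK cells, and 1 at least 2-fold higher, Stmn2 at 1.87, around a median of -0.03 inside the range. Virus set and array cannot be separated in this comparison, and the uninduced OS array is again the array that stood apart. The higher interferon values belong to the uninduced OK array, on which every Sox2-induction value rests.

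The 3-factor states were compared by setting induced OK against induced OS cells, which carried Oct4, Klf4 and Sox2 with a different factor under doxycycline control. Pou5f1 was higher in the induced OK cells by 0.89, so the transcript of delivered Oct4 was not equal in the 3-factor states. The arrays of the 3-factor states were closer than those of the starting states, with Pearson correlations over probesets of 0.985 and 0.961. The starting comparison holds the uninduced OS array, however, and uninduced OK with induced OS cells correlated at 0.980. Closeness of the 3-factor states thus cannot be told from the absence of that array. Epithelial genes were lower and interferon genes higher in OK than in OS cells. Of 19938 genes, 139 were at least 2-fold higher and 241 at least 2-fold lower in OK cells, 1.91% in all, against 0.752% of the dimmest genes. The largest differences upward were those of Sptssb, a subunit of serine palmitoyltransferase, at 4.34, the annexin Anxa10 at 2.97, the intestinal cadherin Cdh17 at 2.91, the matrix protein Efemp1 at 2.73, the carbonic anhydrase Car2 at 2.51 and Calcrl, a receptor for adrenomedullin and calcitonin gene-related peptide, at 2.35. The largest downward were those of S100a14 at -3.59, Krt16 at -3.14, Cd5l at -3.09, Bex1 at -3.01, Krt17 at -2.99 and the kallikrein Klk14 at -2.99. Cd5l and Bex1 lay under the first quartile in OK cells.

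Epithelial genes had 16 of 42 members at least 2-fold lower in induced OK than OS cells and 0 higher, with a median of -0.61; Krt8 differed by -2.85, the tight-junction protein Cldn4 by -2.39 and the protease St14 by -2.18. Squamous epithelial genes had 11 of 27 members at least 2-fold lower and 0 higher around -0.59, with Krt6a at -2.62 and Krt13 at -2.59. Interferon and antiviral genes had 2 of 32 members at least 2-fold higher, Irf7 and Rtp4, both at 1.11, around a median of 0.49. Immediate early genes had 3 of 20 members at least 2-fold lower around -0.33, with the nuclear receptor Nr4a1 at -1.70 and Myc at -1.04. Neural genes had a median of -0.22 and fibroblast surface and identity genes one of 0.22, with the peptidase inhibitor Pi16 at -2.25. The p53 and senescence list had a small median of -0.19, the mitosis list -0.17 and the integrated stress response list -0.16. That of ribosomal protein genes was -0.15, which lay inside the range of unmatched lists at percentile 3.59. All these medians lay outside the central 95% of random lists. Pluripotency genes had a median of -0.13 over 36 members, inside the range, with Tfcp2l1 at least 2-fold lower at -1.18.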

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

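Of the tests in this part, the test of the Sox2-raised genes as a set and the test of the virus set of the induced OS sample were chosen after the result was seen. The subtraction of a trend over gene span and density was added after the data were examined. The X chromosome was chosen after all chromosomes were looked at.

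Named genes that were at least 2-fold higher with Sox2 induction and at least 2-fold lower with Klf4 induction were singled out because their effects had opposite signs; each difference rests on 1 array per group and was not tested. The Sox2 difference minus the Klf4 difference was 5.80 for Fndc3c1, 3.95 for Glb1l2, 3.77 for Gad2, 3.68 for Ednrb, 3.67 for Acss3, 3.65 for Spink10 and 3.63 for Adh7. It was 2.98 for Adgrb3, 2.73 for Prss3, 2.43 for Sfrp4 and 2.39 for Tfcp2l1. Those of Fndc3c1, Spink10 and Adgrb3 are bounds whose rank is not firm, because these genes lay under the first quartile of the uninduced OK array.

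The first pattern weighed is this group of 45 genes with opposite differences, against 4.94 for independent lists. After a trend over gene span and gene density was subtracted, 39 genes had opposite differences against 4.17 for independent lists. The subtraction moved genes by a median of 0.106 at most, so the count could hardly fall. It shows only that a trend of that size does not account for the group as a whole. After quantile normalisation 43 had them, but this moved genes by a median of 0.017 at most on values already normalised, so array scaling stays open. The other 72 genes at least 2-fold higher with Sox2 had a median Klf4 difference of 0.030, inside the range of -0.06 to 0.18 of matched random lists of genes that were not 2-fold lower with Klf4, with 35 below 0 and 37 above, so these genes give no sign of a lowering, though the genes most lowered are left out of them. Whether Sox2 and Klf4 act in opposite ways on the group, GC content and a culture effect on either uninduced array stay open, because each group has 1 array and no genome sequence was used.

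The second pattern is the distance of the uninduced OS array from the other 3. After the trend over span and density was subtracted, 82.5% of the genes at least 2-fold apart with Klf4 induction (1292 of 1567 with a position) were still at least 2-fold apart. This subtraction moved genes by a median of 0.106 at most, so that share could hardly fall far. It shows only that a trend of that size does not account for the distance of the uninduced OS array as a whole. The departure of this array from the mean of the others correlated at 0.723 between the first 2 probesets of 673 brighter genes that have several, against -0.08 to 0.08 for reshuffled pairs, and at 0.552 over the 272 pairs at least 2-fold apart in level, which argues against independent noise over the whole array. X-linked genes had a median Klf4 difference of -0.25 over 325 brighter genes, below the range of -0.07 to 0.06 of autosomal lists matched on span and density, so span and density do not account for the X chromosome. By the labels, the uninduced OS cells alone had no delivered Klf4 switched on. That lack of Klf4, RNA quality, GC content and a culture effect stay open as explanations that may each contribute.

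The third pattern is the source label of the induced OS sample, which names the virus set of the OK cells. With that set the array could be expected to lie with the OK arrays, and it correlated with the uninduced and induced OK arrays at 0.980 and 0.985, against 0.964 with the uninduced OS array, which stood apart alone at 725 genes. At 86 genes both OS arrays lay at least 2-fold to the same side of both OK arrays, against 15 genes that parted induced from uninduced arrays, and the induced OK array correlated more closely with the uninduced OK array, at 0.990, than with the induced OS array. The source label and the title cannot be told apart from these values, because induced OS cells carry the same 3 factors as induced OK cells under either label and no replicate shows how far such arrays differ. The title was followed because all other labels of the sample name the OS set, and every Klf4-induction value depends on it.

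Among the 5443 probesets without a gene name here, which enter no comparison, 37 were at least 2-fold apart with Sox2 induction and 173 with Klf4 induction.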

How the results depend on the processing

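The subtraction of a span and density trend, the removal of the dimmest genes and the second look at the induced comparison were chosen after the data were examined. All other alternatives were planned. No replicate could be left out and no paired analysis was possible because each group has 1 array. All 400 alternative values of 100 named-gene results, from 3 scalings and another probeset rule, stayed within the noise SD of the dimmest genes, and no named gene or list median outside the random range changed sign. The scalings acted on values already normalised, and their largest shift of a comparison median was -0.038, for loess in the uninduced comparison. Most named genes have a single probeset, so the other probeset rule leaves them as they were. This stability is therefore largely built in. Of the list medians, 513 alternatives stayed within the width expected of random lists, and the 27 that did not all came from counting brighter members only. Sign changes occurred 25 times over 19 list medians, 0 of them outside the random range; the small medians of the ribosomal protein and reference lists for Sox2 induction were among those that changed sign under loess. With that filter the epithelial median for Klf4 induction was 1.59 and the squamous one 2.98, as dim members with small differences drop out, and 53 genes were at least 2-fold lower with Sox2 induction in place of 80.

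A different threshold changes the counts by construction. At 1.5-fold there were 545 genes higher and 528 lower with Sox2 induction, 2079 and 2154 with Klf4 induction, 2099 and 2197 in the uninduced and 796 and 955 in the induced comparison, with 137 in the same and 302 in opposite directions. At 3-fold these counts were 27 and 12, 258 and 187, 275 and 328, and 22 and 58, with 4 in the same direction (Ano1, Avil, Tmprss11b and Tubb3) and 2 in opposite directions (Fndc3c1 and Acss3), named after their values were seen; Tmprss11b lay under the first quartile in both uninduced arrays and Fndc3c1 in that of OK cells. Opposite directions thus outnumbered shared ones at 1.5-fold and 2-fold but not at 3-fold, and with Klf4 induction lower genes outnumbered higher ones at 1.5-fold and 2-fold but not at 3-fold; the cause was not tested. Under the 3 scalings the counts stayed within 1.5 times those as deposited, and 626 of 728 genes higher and 666 of 839 lower with Klf4 induction were still called after the span and density trend was subtracted. Without the uninduced OS array no Klf4 induction can be computed. The induced comparison, OK minus OS, leaves that array out and gave medians of -0.59 for squamous and -0.61 for epithelial genes. Both of its arrays hold delivered Klf4, at 7.96 in OK and 8.22 in OS cells, so it does not check the Klf4 induction. Precision at low signal is limited by the arrays, since no measure of signal over background was used.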

Other observations

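The pathway and gene groups in the next paragraph come from lists fixed in advance, and the genes of the later paragraphs were chosen after their values were seen; no test was run on them.

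With Klf4 induction, some single endothelial and adipocyte markers were at least 2-fold higher beside the epithelial genes. Endothelial markers had 5 of 17 members at least 2-fold higher and 0 lower, among them the angiopoietin receptor Tek at 2.51, the VEGF receptor Flt1 at 2.06, Esam at 1.81 and Ramp2 at 1.52, around a median of 0.19 inside the random range. Adipocyte and cartilage markers had 4 of 19 members at least 2-fold higher and 0 lower, the adipogenic transcription factors Cebpa at 1.31 and Pparg at 1.26, the lipase Lpl at 1.25 and the receptor Adipor2 at 1.18, and their median of 0.25 lay above the range, but inside that of unmatched lists at percentile 97.3. BMP pathway genes went both ways around -0.03, with the target gene Id1 at 2.19 against the receptors Bmpr2 at -1.34 and Bmpr1a at -1.22 and the antagonist Grem1 at -1.21. WNT pathway genes had a median of -0.15, inside the matched range but below that of unmatched lists at percentile 2.48, with the secreted inhibitor Notum at 2.66 against the antagonists Frzb at -1.63 and Sfrp4 at -1.24. Among integrated stress response genes the amino acid transporters parted, with Slc7a3 at 1.62 and Slc7a5 at 1.32 against Slc7a11 at -1.79.

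Some genes higher with Sox2 and lower with Klf4 induction are given as single values, since no list or enrichment of their functions was tested. Retinol and retinal dehydrogenases were Adh7 at 2.53 and -1.10, Adh1 at 1.22 and -1.08 and Aldh1a1 at 1.30 and -1.46 for Sox2 and Klf4 induction. The kininogen genes were Kng1 at 1.42 and -1.84 and Kng2 at 1.44 and -1.44, which are close copies whose probes can share signal; Kng1 lay under the first quartile of uninduced OK cells, so its value of 1.42 is a bound. Genes of axon growth and guidance were Slit2 at 1.26 and -1.66, Epha7 at 1.47 and -1.12 and Gap43 at 1.39 and -1.47, and the cytokine genes were Il33 at 1.83 and -1.13 and Il1rn at 1.36 and -1.19. The cell-cycle regulator Rb1 differed by 1.09 and -2.08. Among the 6 genes that went the other way were the epidermal protease Asprv1 at -1.37 and 3.79 and the receptor tyrosine kinase Mst1r at -1.16 and 1.64.

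Of 325 brighter X-linked genes, 65 were at least 2-fold lower with Klf4 induction, and the autosome with the highest share was chromosome 18, at 31 of 269 brighter genes (gene positions from GRCm38.p6). Xist, the RNA of the inactive X chromosome, stood at 5.73 and 6.39 in uninduced and induced OK cells and at 7.42 and 6.08 in uninduced and induced OS cells. The Y-linked genes Uty at 3.61, 3.31, 4.94 and 3.48 and Eif2s3y at 4.30, 4.35, 5.60 and 4.59 in the same order were also highest in uninduced OS cells.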
